A study of Mus musculus with 12 samples.

How the data were processed

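RNA was measured in primary mouse cardiac fibroblasts that had received either a LacZ vector, the control, or vectors for Mef2c, Gata4 and Tbx5 (MGT), and that were collected on day 3, per the labels. The cells came from neonatal mice of postnatal days 1 to 3, adult mice of 3 months and aged mice of 18 months, with 2 libraries in each of the 6 groups. Each title gives the number after the age as the only number that differs between the libraries of a group, and that number is used here as the replicate. The titles all name MGT, also where the treatment field names LacZ, so the vector was taken from the treatment field. The labels do not say whether the libraries of a group are separate animals, separate cultures or repeats of one RNA, so p-values measure the spread between these libraries.

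RNA was extracted with TRIzol, depleted of ribosomal RNA and sequenced from both ends on a HiSeq X10 after a strand-marking library kit, per the labels' protocols. The molecule field names polyadenylated RNA, which sits beside the ribosomal depletion without an explanation in the labels. Reads were trimmed with Trimmomatic 0.36 and counted per gene with featureCounts from Subread 1.5.1 against build mm10, per the submitters' processing notes. The aligner, the annotation release and whether the counting used strand are not given in the sources used here. The authors deposited whole-number counts per gene and library as a single table, per the file headers. The same table holds FPKM, fragment values scaled by exon length and library total, for each library, which the authors computed from those counts, per the file headers. Exon lengths, mm10 coordinates, gene symbols and gene ontology terms are also in the deposited table.

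The table lists 16383 genes in order of Ensembl identifier and stops at ENSMUSG00000057457. Of the 21951 protein-coding genes of GENCODE release M21, 15830 (72.1%) are present, against 15834 whose identifier lies at or before that last one. Genes with later identifiers are not analysed here. They include Actc1, Trp53, Cdkn2b, Ccnd1, Xist, the mitochondrially encoded genes and most replication-dependent histones. All 16383 identifiers lie on the same chromosome in that annotation, 16236 have the same start and end, and 16215 the same symbol. Column sums ran from 12553883 (MGT adult replicate 2) to 16339091 counts (LacZ neonatal replicate 2). Dividing counts by FPKM and exon length for genes with an FPKM of at least 20 gave library totals of 14489848 to 18796716, of which the table holds 86.484% to 87.504%. These totals served as library sizes, and CPM (counts scaled to library size) were computed on them after TMM normalization. A count of 0 in 1 library allows up to 3 counts, or 0.16 to 0.2078 CPM. Intervals and floors cover counting error only.

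Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr kept 11940 genes, and TMM factors ran from 0.9882 to 1.0106. A quasi-likelihood fit with 6 group means over all 12 libraries left 6 residual degrees of freedom and a prior of 12.14. Its biological coefficient of variation was 7.421%. Each of 12 comparisons was a contrast of those means tested with the quasi-likelihood F-test and Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p below 0.05. The standard error of a log2 change was its absolute value divided by the square root of F. The comparisons were MGT against LacZ at each age, each pair of ages under each vector, and the 3 differences between ages in the response to MGT. All adjusted p-values of genes in the text come from this edgeR test.

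Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. Of 31 lists, 26 had at least 3 tested genes. The lists were delivered factors, sarcomere, calcium handling and cardiac channels, cardiac transcription factors and natriuretic peptides, mature cardiomyocyte carry-over, fibroblast identity, fibrillar matrix and cross-linking, myofibroblast activation, senescence cell cycle inhibitors and markers, senescence-associated secretory factors, p53 targets, cell cycle, replication-dependent histones, NR4A and immediate early genes, interferon response, NF-kB targets, complement and antigen presentation, macrophages, lymphocytes, endothelial cells, smooth muscle cells and pericytes, epicardial and mesothelial cells, Schwann cells, erythroid cells, fatty acid oxidation, nuclear-encoded and mitochondrially encoded oxidative phosphorylation, imprinted and fetal growth genes, sex-linked genes, unfolded protein response, and autophagy and lysosome. List medians are also given with genes at 0 counts in a group set to their bound.

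The lists, the comparisons, the test and the rule for naming genes were fixed before the data were examined. The rule takes the 8 largest changes in each direction for MGT against LacZ, 6 for ages and 5 for differences of response, among called genes with at least 5 CPM in the higher group and replicates that do not overlap (differences need the call alone). Predicted and unnamed gene models were left out. It adds 12 genes that are always named (Nr4a3, Mef2c, Gata4, Tbx5, Cdkn1a, Cdkn2a, Tnnt2, Actc1, Myh6, Nppa, Col1a1 and Postn), and from each list the 4 members with the smallest p and up to 2 called against the direction of the list. Fold changes against a group with 0 counts are lower bounds computed against 3 counts over the group, and with 1 to 3 counts the ratio of summed counts over library totals is given with its exact 95% interval.

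Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, a mean of at least 5 CPM, only the compared groups in the fit, the replicate number as a block, and each library left out in turn. Column sums as library totals, and limma voom with quality weights per group, were added after the data were seen. In data simulated for the aged MGT comparison, 99 of 100 genes changed 2-fold and 78 of 100 changed 1.5-fold were called. So were 7 others among 11846 tested. For the aged minus adult difference of responses, 89 and 39 of 100 were called, with 5 others among 11874. Changed genes had a mean of at least 5 CPM, and rates hold for simulated data only. The shifted sarcomere list and 1 other of 26 lists were called.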

Results

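Direct cardiac reprogramming turns a fibroblast into an induced cardiomyocyte by adding heart transcription factors, and the study asked why adult and aged fibroblasts yield less to it than neonatal ones. Its title names the nuclear receptor Nr4a3 and a senescence barrier. RNA was counted in mouse cardiac fibroblasts on day 3 of a LacZ control vector or of Mef2c, Gata4 and Tbx5 together (MGT). There were 2 libraries for each vector at each of 3 ages: neonatal, adult (3 months) and aged (18 months). Column sums of counts were 15357400 and 16339091 for LacZ neonatal, 13648531 and 15200619 for LacZ adult, and 14907462 and 13879198 for LacZ aged. They were 15472772 and 14532766 for MGT neonatal, 13984438 and 12553883 for MGT adult, and 13931316 and 14056483 for MGT aged. Between 13455 and 13981 of the 16383 listed genes had counts in a library. The 10 most abundant genes took 6.127% to 8.726% of a library, led by Fn1, Thbs1 or Eef1a1, at most 2.626% (Fn1 in LacZ neonatal replicate 2). The first principal component (47.6% of the variance) placed the 4 neonatal libraries between -59.0 and -53.2 and the 8 adult and aged ones between 14.2 and 43.7. The second (23.5%) separated LacZ, between 9.1 and 42.9, from MGT, between -41.0 and -12.8. The third (13.0%) separated adult, between -33.5 and -19.7, from aged, between 13.1 and 32.8. Replicates differed by more than counting error in every group, from a chi-square per degree of freedom of 2.284 in LacZ neonatal to 21.197 in LacZ adult. Each age came from its own cell preparations, so age and preparation cannot be told apart in any comparison of ages.

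**Figure D1:**
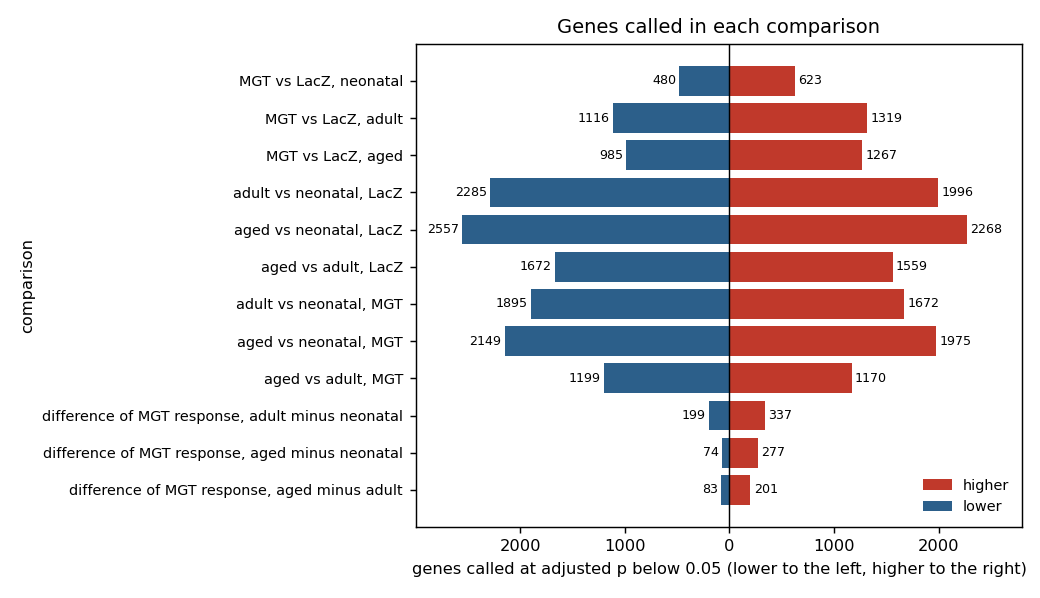
Number of genes called lower (left) and higher (right) in each of the 12 comparisons at an adjusted p below 0.05. The most calls, 4825, were between aged and neonatal LacZ cells, and MGT against LacZ called 2435 in adult cells.

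Nr4a3, an orphan nuclear receptor of the NR4A family that many cells induce within minutes of a stimulus, rose with MGT at every age. The gene (ENSMUSG00000028341) lies on mm10 chromosome 4 from 48045153 to 48086447. It measured 9.13 ± 1.4 CPM under MGT against 2.77 ± 0.079 under LacZ in neonatal cells (mean ± SD, n = 2), a log2 change of 1.72 ± 0.24 (SE, adjusted p = 5.1e-05). In adult cells it measured 41.2 ± 5.1 against 12.3 ± 1.5 CPM, a log2 change of 1.74 ± 0.17 (adjusted p = 4.6e-07), and in aged cells 27.5 ± 6.8 against 10.1 ± 2.3 CPM, a change of 1.45 ± 0.18 (adjusted p = 1.2e-05). The log2 response did not differ detectably between ages (adult minus neonatal 0.02 ± 0.35, adjusted p = 0.99, aged minus neonatal -0.27 ± 0.3, adjusted p = 0.73, aged minus adult -0.29 ± 0.25, adjusted p = 0.69). Its starting level did: under LacZ it lay 2.15 ± 0.23 log2 units higher in adult (adjusted p = 4.9e-07) and 1.86 ± 0.24 higher in aged (adjusted p = 3.9e-06) than in neonatal cells, while aged and adult did not differ detectably (-0.29 ± 0.19, adjusted p = 0.28). Under MGT it lay 2.17 ± 0.18 higher in adult and 1.59 ± 0.18 higher in aged than in neonatal cells. Aged MGT cells had less of it than adult ones (-0.58 ± 0.16, adjusted p = 0.016), a call that was lost without MGT adult replicate 2 (-0.45) or MGT aged replicate 1 (-0.37). Nr4a1, its close relative, rose by 1.3 ± 0.14 with MGT in neonatal cells (48.3 to 119 CPM, adjusted p = 2.7e-06) and was 2.59 ± 0.14 higher in adult than in neonatal LacZ cells (adjusted p = 5.8e-11). The list of NR4A and immediate early genes as a whole was not called for MGT at any age (adjusted p = 0.098, 0.76 and 0.7 in neonatal, adult and aged cells).

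The delivered factors themselves were measured at similar levels in MGT cells of each age, against LacZ levels that were lower in adult and aged than in neonatal cells. These counts cannot separate vector-derived from endogenous transcripts. Tbx5 (ENSMUSG00000018263, chromosome 5, 119832668 to 119885219), a factor of the heart fields, reached 243 ± 36, 284 ± 7.2 and 272 ± 39 CPM in neonatal, adult and aged MGT cells against 2.2 ± 0.32, 1.0 ± 0.3 and 0.603 ± 0.2 under LacZ. Its log2 changes were 6.78 ± 0.17 (adjusted p = 4.1e-15), 8.16 ± 0.19 (6.7e-16) and 8.81 ± 0.2 (5.7e-16). Mef2c (ENSMUSG00000005583, chromosome 13, 83504034 to 83667080), a muscle activator, reached 198 ± 28, 208 ± 9.2 and 166 ± 21 CPM from 17.3 ± 1.2, 9.5 ± 0.84 and 9.19 ± 1.6, changes of 3.52 ± 0.13 (8.1e-13), 4.45 ± 0.14 (4.5e-14) and 4.18 ± 0.14 (1.1e-13). Gata4 (ENSMUSG00000021944, chromosome 14, 63198922 to 63271692), a zinc finger activator that cardiac fibroblasts already express, rose least, to 286 ± 25, 237 ± 1.8 and 234 ± 24 CPM from 159 ± 6.9, 119 ± 4.6 and 111 ± 0.36. Its changes were 0.85 ± 0.09 (1.5e-06), 0.99 ± 0.09 (1.1e-07) and 1.07 ± 0.09 (5.9e-08). Taken as a list, the 3 factors had median log2 changes of 3.52, 4.45 and 4.18 (adjusted p = 1.4e-59, 1.3e-40 and 1.4e-50, all 3 genes called at each age). Under LacZ all 3 were lower in adult than in neonatal cells (Mef2c -0.87 ± 0.15, Gata4 -0.41 ± 0.09, Tbx5 -1.15 ± 0.33, adjusted p = 0.00014, 0.0012 and 0.0098), the Tbx5 call being lost without LacZ neonatal replicate 1 (-0.98) or LacZ adult replicate 2 (-0.85). They were lower in aged than in neonatal LacZ cells as well (-0.92 ± 0.15, -0.51 ± 0.09 and -1.86 ± 0.37), and none differed detectably between aged and adult LacZ cells (adjusted p = 0.86, 0.44 and 0.25). Between MGT cells Tbx5 did not differ detectably by age (0.23 in adult and 0.16 in aged against neonatal, adjusted p = 0.13 and 0.27). Gata4 was lower in adult (-0.27 ± 0.09, adjusted p = 0.026) and aged (-0.29, adjusted p = 0.015) than in neonatal MGT cells. The adult call was lost without MGT neonatal replicate 2 (-0.17) or MGT adult replicate 1 (-0.28) or 2 (-0.26), and the aged call without MGT neonatal replicate 2 or MGT aged replicate 1 (-0.20 each). Mef2c was lower in aged than in adult MGT cells (-0.32, adjusted p = 0.046), which was lost without MGT adult replicate 1 (-0.28) or 2 (-0.37) or MGT aged replicate 1 (-0.22).

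**Figure D2:**
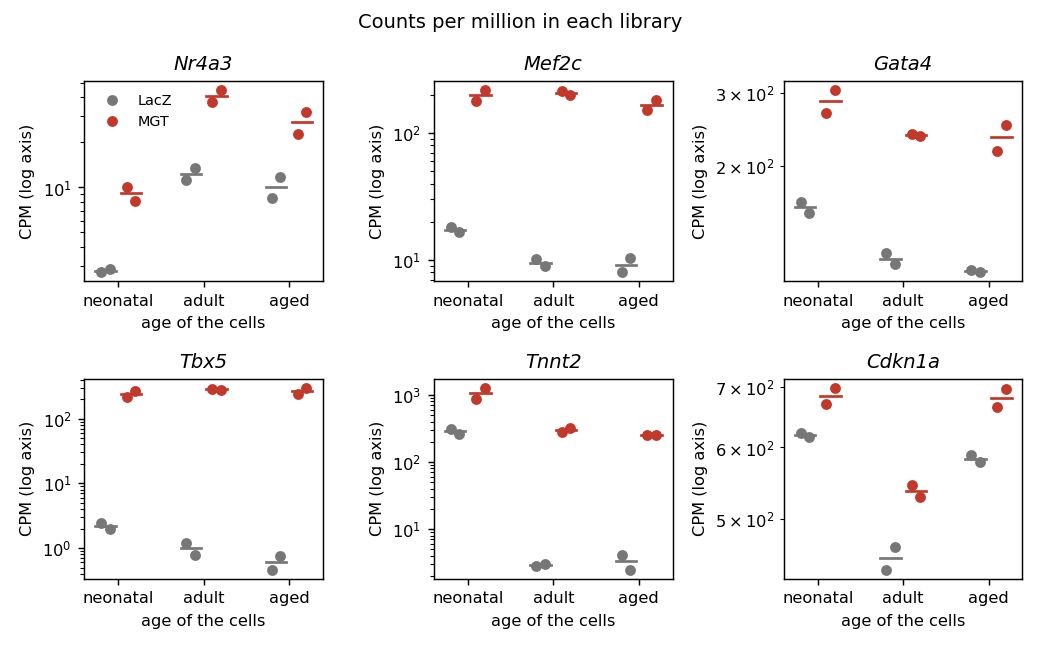
CPM on log axes in each of the 12 libraries for Nr4a3, the delivered Mef2c, Gata4 and Tbx5, the troponin Tnnt2 and the cell cycle inhibitor Cdkn1a. Points are libraries (LacZ grey, MGT red) and bars are the means of 2 libraries. Nr4a3 starts from a higher level in adult and aged cells, and Tnnt2 from a lower one.

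In neonatal cells MGT raised contractile and calcium cycling genes. Mesothelial and complement genes fell. Loss of mesothelial cells was not tested as a cause. Of 11940 tested genes 1103 were called, 623 higher and 480 lower, and 264 and 118 of these moved at least 2-fold. The count was 642 without LacZ neonatal replicate 1, 645 without LacZ neonatal replicate 2 and 628 without MGT neonatal replicate 2. It was 1688 with only the compared groups in the fit and 1817 with voom weights. Muscle genes were among the largest rises. Xirp2 (ENSMUSG00000027022, chromosome 2, 67173834 to 67526615), which ties actin to the intercalated disc, went from 0.776 ± 0.34 to 71.3 ± 27 CPM (6.52 ± 0.33, adjusted p = 7.9e-11). The stretch-responsive Smpx rose by 7.06 ± 0.33 (adjusted p = 2.1e-10), the muscle LIM protein gene Csrp3 by 6.46 ± 0.35 (1.8e-10) and the Z-disc gene Synpo2l by 6.45 ± 0.2 (6e-14). The adenosine receptor gene Adora1 had 0 counts under LacZ and rose at least 73.4-fold (6.09 ± 1.5 CPM, adjusted p = 2.4e-07). The secretory granule gene Scg2 rose by 5.99 ± 0.27, and the skeletal myosin gene Myh1, which sits in a cluster of similar genes, by 5.89 ± 0.3. Among falls, the dipeptidyl peptidase gene Dpp4, a marker of a progenitor-type fibroblast, dropped from 31.4 ± 0.26 to 3.91 ± 0.61 CPM (-3.01 ± 0.17, adjusted p = 2.5e-10), and the prostaglandin-degrading Hpgd from 24.8 ± 0.41 to 2.84 ± 0.6 CPM (-3.12 ± 0.18, 4.2e-10). Ddx4 (-3.63 ± 0.35), Slc4a10 (-3.45 ± 0.41), Cyp2s1 (-3.17 ± 0.26), Vat1l (-2.98 ± 0.26), Vstm2a (-2.98 ± 0.37) and Krt14 (-2.95 ± 0.37) fell as well, from lower levels under LacZ.

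Of 27 tested sarcomere genes 22 rose in neonatal cells and 5 were not called, 22 also adjusted over the list alone (median 1.91, camera adjusted p = 1.4e-95). They included Des, the intermediate filament of muscle (14.7 to 281 CPM, 4.26 ± 0.12, adjusted p = 1e-14), and Myom2 of the M-band (2.61 to 104 CPM, 5.31 ± 0.19). Tnnt2 (ENSMUSG00000026414, chromosome 1, 135836354 to 135852260), the cardiac troponin T gene, rose from an already high 285 ± 32 to 1070 ± 280 CPM (1.91 ± 0.14, adjusted p = 1.1e-08). The adult atrial and ventricular myosin gene Myh6 did not change detectably (8.07 against 7.94 CPM, 0.02 ± 0.23, adjusted p = 0.98). Among 23 calcium handling and channel genes 15 rose and 8 were not called, 15 adjusted over the list alone (median 1.06, adjusted p = 1.5e-20), such as the calcium release channel Ryr2 (1.04 to 25.9 CPM, 4.62 ± 0.23) and the calcium store protein Casq2 (2.62 to 36.0 CPM, 3.77 ± 0.23). Of 14 cardiac transcription factors and natriuretic peptides 6 rose and 1 fell, the same numbers adjusted over the list alone (median 0.22, adjusted p = 0.0044, but adjusted p = 0.06 with an estimated correlation). Nppa, the atrial peptide, rose from 4.18 ± 0.87 to 16.3 ± 4.5 CPM (1.95 ± 0.25, adjusted p = 3.2e-05). The 6 became 3 without either LacZ neonatal replicate.

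The epicardial and mesothelial list fell most in neonatal cells, with 9 of 13 genes lower and 2 higher, 9 and 2 adjusted over the list alone (median -1.44, adjusted p = 9.9e-18). The mesothelial membrane genes Upk3b (138 to 47.9 CPM, -1.53 ± 0.09) and Lrrn4 (253 to 63.9 CPM, -1.98 ± 0.12) led it, while Krt19 rose (6.01 to 13.0 CPM, 1.11 ± 0.17). Of 38 interferon response genes 26 fell and 12 were not called, 32 adjusted over the list alone (median -0.51, adjusted p = 7.6e-15, adjusted p = 0.21 with an estimated correlation). Rsad2, an antiviral enzyme, fell from 147 to 80.4 CPM (-0.87 ± 0.15, adjusted p = 0.00065). Without LacZ neonatal replicate 2 the 26 became 9, without MGT neonatal replicate 2 they became 7, and DESeq2 called 15. Complement and antigen presentation had 5 of 9 lower, 6 adjusted over the list alone (median -0.64, adjusted p = 6.5e-08), led by the C1 inhibitor Serping1 (389 to 206 CPM, -0.92 ± 0.1). Fibroblast identity genes split, with 10 of 21 lower and 3 higher, 11 and 4 adjusted over the list alone (median -0.49, adjusted p = 3.1e-05, adjusted p = 0.061 with an estimated correlation), the 10 becoming 5 without LacZ neonatal replicate 1. The proteoglycan Lum (37.5 to 8.11 CPM, -2.21 ± 0.14) and the fibroblast factor Tcf21 (224 to 119 CPM, -0.92 ± 0.12) fell, and the surface glycoprotein Thy1 rose (268 to 438 CPM, 0.71 ± 0.09). Fibrillar matrix had 7 of 24 lower and 2 higher, likewise adjusted over the list alone (median -0.13, adjusted p = 0.003, adjusted p = 0.49 with an estimated correlation), and the 7 became 3 without LacZ neonatal replicate 1 or 2 or MGT neonatal replicate 2. Elastin Eln (51.4 to 20.6 CPM, -1.32 ± 0.12) and Col3a1 (1990 to 1030 CPM, -0.95 ± 0.1) fell, whereas Col1a1 (-0.1 ± 0.1, adjusted p = 0.7) and Postn (-0.11 ± 0.09, adjusted p = 0.62) were not called. Myofibroblast activation genes moved up, 8 of 21 higher and 1 lower, 9 and 1 adjusted over the list alone (median 0.11, adjusted p = 0.00022), among them Cthrc1 (31.5 to 118 CPM, 1.9 ± 0.11) and the ligand gene Tgfb2 (72.8 to 181 CPM, 1.31 ± 0.12). That 8 was 4 without either LacZ neonatal replicate, 5 without MGT neonatal replicate 1 and 3 without MGT neonatal replicate 2.

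In adult cells MGT called 2435 genes (1319 higher and 1116 lower, 510 and 209 at least 2-fold). The count was 1475 without MGT adult replicate 1 and 1591 without replicate 2. With only the compared groups in the fit it was 1550 and with voom weights 1758, each fewer than in neonatal cells. Muscle genes came up from near absence, while interferon response genes fell. Xirp2 went from 0.092 CPM (3 counts over both libraries) to 191 ± 15 CPM, a ratio of 2130 (95% counting interval 729 to 10300, adjusted p = 7.1e-13). The atrial myosin light chain gene Myl7 (18.3 ± 0.23 CPM) and Smpx (10.6 CPM) had 0 counts under LacZ and rose at least 204-fold and 119-fold. Csrp3, the potassium channel gene Kcna6 and the signalling ligand gene Wnt7a had ratios of 481 (85.9 to 19000), 350 (62.3 to 13900) and 195 (53.6 to 1620), each against 1 or 2 counts. Myom2 rose from 0.697 ± 0.19 to 115 ± 3.8 CPM (7.37 ± 0.24, adjusted p = 5.7e-14). The largest fall was in the antiviral GTPase gene Mx1 (ENSMUSG00000000386, chromosome 16, 97447035 to 97462907), from 14.9 ± 3.7 to 1.04 ± 0.2 CPM (-3.82 ± 0.34, adjusted p = 1.2e-07). Mx1 has a near relative, Mx2, with which it could share reads. The chemokine Cxcl10 (48.7 ± 1.4 to 6.56 ± 2 CPM, -2.88 ± 0.23), Rsad2 (146 ± 19 to 27.9 ± 3.1 CPM, -2.38 ± 0.17) and Cmpk2 (58.4 to 11.5 CPM, -2.35 ± 0.19) fell with it. The Wnt modulator Sfrp2 (-2.66 ± 0.19), the hypoxia-linked mitochondrial gene Ndufa4l2 (-2.6 ± 0.21), the fibroblast collagen gene Col14a1 (-2.49 ± 0.24) and the oxysterol hydroxylase gene Cyp7b1 (-2.47 ± 0.24) made up the rest of the 8.

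Of 27 sarcomere genes 21 rose in adult cells and 6 were not called (22 higher and 1 lower adjusted over the list alone), with a median of 3.78, or 3.42 with genes at 0 counts set to their bound (adjusted p = 6.2e-63). Des went from 3.89 to 266 CPM (6.09 ± 0.14), and Tnnt2 from 2.9 ± 0.12 to 296 ± 27 CPM (6.67 ± 0.21, adjusted p = 4.5e-14). Myh6 had 0 counts in all 4 adult libraries. Calcium handling and channel genes had 15 of 23 higher, 17 adjusted over the list alone (median 1.86, adjusted p = 4.7e-15), with Ryr2 from 0.244 to 14.2 CPM (5.85 ± 0.33). Cardiac transcription factors and natriuretic peptides had 5 of 14 higher and 2 lower, 5 and 3 adjusted over the list alone (median 0.19, adjusted p = 0.0076, adjusted p = 0.071 with an estimated correlation and 0.074 without LacZ adult replicate 2). Nppa rose from 0.128 ± 0.18 to 4.0 ± 0.22 CPM (4.97 ± 0.57, adjusted p = 3.4e-06). Interferon response genes fell across the list, 36 of 38, and all 38 adjusted over the list alone (median -1.27, adjusted p = 4.1e-43), including the peptide transporter Tap1 (85.7 to 33.7 CPM, -1.35 ± 0.1). Complement and antigen presentation had 6 of 9 lower, 7 adjusted over the list alone (median -0.56, adjusted p = 3.5e-06), such as the class I gene H2-Q4 (145 to 57.7 CPM, -1.33 ± 0.11). Fibroblast identity had 11 of 21 lower and 3 higher, 12 and 4 adjusted over the list alone (median -0.63, adjusted p = 8e-07), with Tcf21 from 180 to 71.3 CPM (-1.34 ± 0.12) and Thy1 from 164 to 552 CPM (1.75 ± 0.09).

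Fibrillar matrix fell in adult cells, 13 of 24 lower and 3 higher, 17 and 4 adjusted over the list alone (median -0.33, adjusted p = 1.4e-05, adjusted p = 0.26 with an estimated correlation). The 3 higher became 1 without LacZ adult replicate 2 or MGT adult replicate 2. Col3a1 went from 4160 to 1610 CPM (-1.37 ± 0.1) and Postn from 284 ± 30 to 174 ± 20 CPM (-0.71 ± 0.1, adjusted p = 2e-05), whereas Col12a1 rose from 648 to 1680 CPM (1.38 ± 0.16) and Col1a1 was not called (0.22 ± 0.1, adjusted p = 0.13). Myofibroblast activation had 8 of 21 higher and 3 lower, 9 and 3 adjusted over the list alone (median 0.25, adjusted p = 0.00013), led by Cthrc1 (33.7 to 210 CPM, 2.64 ± 0.12). Cell cycle genes had 21 of 49 lower, 29 adjusted over the list alone (median -0.28, adjusted p = 1.1e-05, adjusted p = 0.28 with an estimated correlation), among them the spindle gene Nusap1 (45.3 to 28.7 CPM, -0.66 ± 0.11) and cyclin gene Ccnb2 (80.4 to 55.8 CPM, -0.53 ± 0.1). The 21 became 13 without MGT adult replicate 1 and 6 without replicate 2. Endothelial genes had 4 of 16 higher and 2 lower, 5 and 2 adjusted over the list alone (median 0.56, adjusted p = 0.004, adjusted p = 0.26 with an estimated correlation), with the VEGF receptor gene Flt1 from 1.53 to 59.2 CPM (5.27 ± 0.18) and the phosphatase gene Ptprb falling from 156 to 92.4 CPM (-0.76 ± 0.1). Epicardial genes had 4 of 13 higher and 3 lower, 5 and 3 adjusted over the list alone (median 1.1, floored 1.07, adjusted p = 0.0054, adjusted p = 0.12 with an estimated correlation and 0.1 without LacZ adult replicate 1), with Upk1b from 0.845 to 33.7 CPM (5.32 ± 0.19). NF-kB targets were not called as a list (adjusted p = 0.36), although prostaglandin synthase Ptgs2 rose from 198 to 1300 CPM (2.71 ± 0.12) and the acute phase gene Saa3 to 539 CPM (2.43 ± 0.15). Macrophage, smooth muscle, oxidative phosphorylation and autophagy lists were not called (adjusted p = 0.072, 0.87, 0.071 and 0.13).

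In aged cells MGT again raised muscle genes, but its largest falls were smaller than in adult cells and lay outside the interferon response. It called 2252 genes, 1267 higher and 985 lower, of which 407 and 36 moved at least 2-fold. The count was 1268 without LacZ aged replicate 1, 1221 without LacZ aged replicate 2 and 1196 without MGT aged replicate 2. Xirp2 went from 0.436 ± 0.53 to 231 ± 17 CPM (8.99 ± 0.34, adjusted p = 8.5e-13), and Synpo2l from 0.33 ± 0.058 to 75.4 ± 7.8 CPM (7.81 ± 0.26). Smpx (8.18 CPM) and the pacemaker channel gene Hcn4 (5.44 ± 2.3 CPM) had 0 counts under LacZ and rose at least 91.2-fold and 60.7-fold. Against 1 count each, Myl7 had a ratio of 459 (81.9 to 18200), Csrp3 of 252 (44.7 to 9970) and the potassium channel gene Kcnc4 of 168 (29.8 to 6690). Among the falls, the secreted Wnt antagonist gene Dkk2 went from 8.51 ± 0.65 to 2.27 ± 0.085 CPM (-1.91 ± 0.22, adjusted p = 5e-06) and Sfrp1 from 199 ± 52 to 66.7 ± 0.2 CPM (-1.57 ± 0.15, 2.7e-07). Ripor2 (-1.91 ± 0.21), the vesicle gene Rab3c (-1.87 ± 0.24), creatine synthesis gene Gamt (-1.43 ± 0.25), Tmem35a (-1.39 ± 0.25) and Clca3a1 (-1.36 ± 0.1) fell too. The growth arrest gene Gas1 fell (-1.48 ± 0.32, adjusted p = 0.0033), a call lost without LacZ aged replicate 2 (-0.84) or MGT aged replicate 1 (-1.24).

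Sarcomere genes had 20 of 27 higher in aged cells (20 and 1 lower adjusted over the list alone), with a median of 3.23, floored 3.14 (adjusted p = 4.5e-75). Des went from 3.74 to 252 CPM (6.07 ± 0.14) and Tnnt2 from 3.29 ± 1.2 to 252 ± 5.1 CPM (6.25 ± 0.2, adjusted p = 8.6e-14), while Myh6 had 2 counts against 1. Calcium handling and channel genes had 11 of 23 higher, 14 adjusted over the list alone (median 1.43, floored 1.41, adjusted p = 8.7e-14). Cardiac transcription factors and natriuretic peptides had 5 of 14 higher (also adjusted over the list alone, median 0.17, adjusted p = 0.0025, 0.064 with an estimated correlation), and Nppa rose at least 15.8-fold from 0 counts to 1.42 ± 0.22 CPM (adjusted p = 0.00024). Mature cardiomyocyte genes had 4 of 9 higher (also adjusted over the list alone, median 1.19, floored 1.18, adjusted p = 1.5e-06, 0.064 with an estimated correlation). Under MGT Myh6, Actn2, Tnni3 and Myl2 lay at or below 0.283 CPM, Tnnt2 at 252 and Myl7 at 13.7. Cell cycle genes fell widely, 40 of 49, and 43 adjusted over the list alone (median -0.46, adjusted p = 5.4e-20, 0.064 with an estimated correlation). Their fall was larger than in adult cells by a median of -0.22 (adjusted p = 4.8e-07, adjusted p = 0.34 with an estimated correlation). The survivin gene Birc5 fell from 75.7 to 43.1 CPM (-0.81 ± 0.1), Ccnb2 from 78.1 to 44.8 CPM (-0.8 ± 0.1) and the kinase gene Cdk1 from 152 to 96.4 CPM (-0.66 ± 0.09). Interferon response genes had 8 of 38 lower, 8 adjusted over the list alone (median -0.32, adjusted p = 0.0025, adjusted p = 0.66 with an estimated correlation). The 8 became 13 without LacZ aged replicate 1 and 1 without MGT aged replicate 2, and none was left without LacZ aged replicate 2 (list adjusted p = 0.79) or MGT aged replicate 1 (0.096). Nuclear-encoded oxidative phosphorylation had 14 of 47 lower, 14 adjusted over the list alone (median -0.2, adjusted p = 6e-06, adjusted p = 0.63 with an estimated correlation), such as the complex I gene Ndufa5 (-0.58 ± 0.11). It was 2 without LacZ aged replicate 1 and 8 without LacZ aged replicate 2 or MGT aged replicate 2.

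Matrix in aged cells moved up more than down under MGT, the list as a whole not being called (8 of 24 higher, 5 lower, 11 and 6 adjusted over the list alone, adjusted p = 0.37). The 8 became 5 without LacZ aged replicate 1, and the 5 became 1 without LacZ aged replicate 2 or MGT aged replicate 1. Col1a1, the main fibrillar collagen gene, rose from 2760 ± 240 to 4670 ± 800 CPM (0.76 ± 0.1, adjusted p = 2.7e-05), and the cross-linking enzyme Loxl2 from 233 to 369 CPM (0.66 ± 0.08), while Postn was not called (0.09 ± 0.1, adjusted p = 0.55). Myofibroblast activation had 12 of 21 higher and 1 lower, also adjusted over the list alone (median 0.33, adjusted p = 2.6e-09), with Cthrc1 from 8.07 to 75.8 CPM (3.23 ± 0.14) and Tgfb3 from 49.5 to 187 CPM (1.92 ± 0.1). Smooth muscle and pericyte genes had 3 of 12 higher (3 and 1 lower adjusted over the list alone, median 0.42, adjusted p = 0.0016, adjusted p = 0.21 with an estimated correlation), led by Cspg4 (4.65 to 65.8 CPM, 3.82 ± 0.17). Epicardial genes had 3 of 13 higher and 1 lower (also adjusted over the list alone, median 0.0, floored 0.07, adjusted p = 0.018, adjusted p = 0.21 with an estimated correlation and 0.077 without LacZ aged replicate 1). Fibroblast identity, complement and macrophage lists were not called (adjusted p = 0.3, 0.73 and 0.3).

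The ages shared much of the response to MGT. Muscle genes such as Des, Myom2, Smpx, Xirp2, Csrp3 and Synpo2l rose at every age, and 409 genes rose and 132 fell at all 3. Neonatal and adult cells shared 486 of their rises against 68.8 that independent lists of those sizes would share, and 271 of their falls against 44.9. Neonatal and aged cells shared 452 (66.1) and 150 (39.6), and adult and aged cells 788 (140.0) and 393 (92.1). Among opposite calls 34 fell in neonatal and rose in adult cells and 6 did the reverse. Likewise 32 fell in neonatal and 16 in adult cells but rose in aged cells. No expected number was computed for these. No library enters both sides of these comparisons. Across the 11940 tested genes, which are not independent replicates, log2 responses correlated at r = 0.578 between adult and neonatal cells, 0.543 between aged and neonatal and 0.713 between aged and adult. They had the same sign in 64.9%, 64.4% and 70.6% of genes.

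Adult and neonatal LacZ cells, compared to describe the starting population, differed in markers of other lineages and in inflammatory genes. Neonatal cells carried far more transcripts of endothelial, epicardial, smooth muscle, cardiomyocyte and imprinted growth genes, and somewhat more of p53 targets. Adult cells carried more of the fibroblast programme, of secreted inflammatory factors and of complement. The test called 4281 genes, 1996 higher and 2285 lower in adult cells, 586 and 859 of them at least 2-fold. Mmp3 (ENSMUSG00000043613, chromosome 9, 7445822 to 7455975), a matrix-degrading stromelysin, rose from 31.1 ± 1.8 to 1970 ± 300 CPM (5.98 ± 0.13, adjusted p = 2e-16). The chemokine genes Ccl11 and Ccl8, members of a family with close relatives, had ratios of 233 (41.4 to 9260) and 162 (55.2 to 791). The alkaline phosphatase gene Alpl rose by 5.93 ± 0.26, Stac2 by 5.26 ± 0.23 and Ly6k, in another family of similar genes, by 5.13 ± 0.33. Krt8 (ENSMUSG00000049382, chromosome 15, 101996698 to 102004482), a keratin of simple epithelia, had 0 counts in adult cells against 15.6 CPM and was at least 174-fold lower (adjusted p = 3.4e-10). Myl7 was at least 97.5-fold lower, Myh6 at least 88.4-fold and Krt14 at least 63.0-fold. The epithelial factor gene Bnc1, with 2 counts in adult cells, was lower by a ratio of 785 (217 to 6490), and Vat1l, with 1 count, by 560 (100 to 22200). Tnnt2 lay at 2.9 CPM in adult against 285 in neonatal cells (-6.61 ± 0.2, adjusted p = 2.7e-14), and Nppa fell by 5.04 ± 0.55 on the log2 scale (adjusted p = 1e-06).

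Lineage lists gave the widest differences between adult and neonatal LacZ cells. Endothelial genes had 14 of 16 lower in adult cells (14 and 1 higher adjusted over the list alone, median -3.84, adjusted p = 2.8e-36), among them Pecam1 (66.7 to 2.7 CPM, -4.61 ± 0.19) and Emcn (81.6 to 1.19 CPM, -6.08 ± 0.19). Epicardial genes had 10 of 13 lower and 2 higher, 10 and 2 adjusted over the list alone (median -6.64, adjusted p = 7e-33), such as Upk3b (138 to 1.77 CPM, -6.28 ± 0.14), whereas the retinoic acid enzyme gene Aldh1a2 rose from 51.4 to 482 CPM (3.23 ± 0.1). Smooth muscle and pericyte genes had 8 of 12 lower and 3 higher, 9 and 3 adjusted over the list alone (median -1.98, adjusted p = 3e-11), including Mcam (125 to 5.68 CPM, -4.46 ± 0.11). Sarcomere genes had 18 of 27 lower, 21 adjusted over the list alone (median -2.45, floored -1.91, adjusted p = 2e-11), and mature cardiomyocyte genes 3 of 9 (median -1.04, adjusted p = 0.00024, adjusted p = 0.12 with an estimated correlation), or 5 without LacZ adult replicate 1. Cardiac transcription factors had 8 of 14 lower, 8 adjusted over the list alone (median -0.86, adjusted p = 0.00031), with Gata6 falling. Imprinted and fetal growth genes had 13 of 16 lower and 1 higher, likewise adjusted over the list alone (median -1.77, adjusted p = 5.2e-17), with Plagl1 from 94.9 to 7.13 CPM (-3.74 ± 0.14). Macrophage genes had 6 of 19 higher and 3 lower, 7 and 3 adjusted over the list alone (median 0.36, adjusted p = 0.022, adjusted p = 0.54 with an estimated correlation), with Pf4 from 9.75 to 58.8 CPM. That list call was lost without LacZ neonatal replicate 1 (0.13), and the 3 became 1 without LacZ neonatal replicate 2.

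Adult LacZ fibroblasts had more of their own markers and of inflammatory genes than neonatal ones, and less of a contractile signature. Fibroblast identity had 15 of 21 higher and 3 lower, 15 and 4 adjusted over the list alone (median 1.06, adjusted p = 1.7e-15), such as the receptor gene Pdgfra (197 to 917 CPM, 2.22 ± 0.09). Myofibroblast genes had 13 of 21 lower and 2 higher, 14 and 2 adjusted over the list alone (median -0.58, adjusted p = 2e-08), including the smooth muscle actin gene Acta2 (2760 to 1030 CPM, -1.42 ± 0.08), and Postn (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037), a matricellular gene of activated fibroblasts, went from 2270 ± 8.7 to 284 ± 30 CPM (-3.0 ± 0.1, adjusted p = 5.8e-14). Col1a1 fell as well (6300 ± 7.1 to 4150 ± 380 CPM, -0.6 ± 0.1, adjusted p = 9.8e-05), while the matrix list was not called (median 0.1, although the test pointed down, adjusted p = 0.47). NF-kB targets had 16 of 27 higher and 3 lower, 17 and 3 adjusted over the list alone (median 0.43, adjusted p = 2.1e-08), with the pentraxin gene Ptx3 from 164 to 2000 CPM (3.6 ± 0.11). Complement had 7 of 9 higher, 8 adjusted over the list alone (median 0.9, adjusted p = 7.8e-06), with C3 from 128 to 778 CPM (2.6 ± 0.12). NR4A and immediate early genes had 16 of 26 higher and 5 lower, 17 and 5 adjusted over the list alone (median 0.29, adjusted p = 0.00045, adjusted p = 0.22 with an estimated correlation). Interferon response had 13 of 38 higher and 3 lower, likewise adjusted over the list alone (median 0.21, adjusted p = 0.047, adjusted p = 0.72 with an estimated correlation), lost without LacZ neonatal replicate 1 (0.13) or LacZ adult replicate 1 (0.076), and the 3 became none without LacZ neonatal replicate 2.

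Aged LacZ cells differed from neonatal ones in the same lineages and in addition had little of the interferon response. The test called 4825 genes, 2268 higher and 2557 lower in aged cells, 494 and 1071 at least 2-fold. All 38 interferon response genes were lower, also adjusted over the list alone (median -3.07, adjusted p = 2.2e-77), for example Ifi44 (166 to 5.27 CPM, -4.98 ± 0.17), the tetherin gene Bst2 (425 to 41.1 CPM, -3.37 ± 0.12) and the ubiquitin-like modifier Isg15 (271 to 15.5 CPM, -4.13 ± 0.16). Rises were led by the steroid-metabolising Akr1c18 (5.65 ± 0.37), the fibroblast growth factor gene Fgf10 (0.601 to 27.0 ± 2.3 CPM, 5.46 ± 0.2, adjusted p = 8.6e-14), the chemokine gene Cxcl14 (5.03 ± 0.26), Prl2c3 (4.99 ± 0.39), Alpl (4.83 ± 0.28) and Sprr2h (4.76 ± 0.41). Akr1c18, Prl2c3 and Sprr2h belong to clusters of near-identical genes between which reads can be divided. Krt8 was at least 174-fold and Krt14 at least 63.1-fold lower. The membrane glycoprotein gene Gpm6a fell from 73.4 ± 9.7 to 0.12 CPM (-9.17 ± 0.29) and Bnc1 from 47.1 ± 3.4 to 0.173 CPM (-7.98 ± 0.37). With 1 count each, Vat1l, Myl7 and Myh6 were lower by ratios of 561 (100 to 22200), 293 (52.2 to 11600) and 265 (47.3 to 10500). Nppa was at least 46.8-fold lower, and Tnnt2 fell by 6.42 ± 0.2 on the log2 scale. Endothelial genes had 14 of 16 lower and 1 higher, 15 and 1 adjusted over the list alone (median -4.7, adjusted p = 2e-35). Epicardial genes had 9 of 13 lower and 2 higher, also adjusted over the list alone (median -6.23, adjusted p = 1.9e-27). Smooth muscle genes had 9 of 12 lower and 1 higher, 9 and 2 adjusted over the list alone (median -1.82, adjusted p = 2.8e-09). Imprinted genes had 15 of 16 lower and 1 higher, also adjusted over the list alone (median -1.95, adjusted p = 3.4e-18). Sarcomere genes had 18 of 27 lower, 20 and 1 higher adjusted over the list alone (median -2.2, floored -1.97, adjusted p = 1.2e-07, adjusted p = 0.13 with an estimated correlation).

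Matrix genes were lower in aged than in neonatal LacZ cells, 17 of 24 with 1 higher, also adjusted over the list alone (median -0.55, adjusted p = 2.3e-07, adjusted p = 0.18 with an estimated correlation), among them Eln (51.4 to 1.55 CPM, -5.04 ± 0.17). Col1a1 fell by 1.19 ± 0.1 on the log2 scale (adjusted p = 1.8e-08) and Postn from 2270 to 161 ± 18 CPM (-3.82 ± 0.11). Myofibroblast genes had 12 of 21 lower and 4 higher, also adjusted over the list alone (median -0.45, adjusted p = 4.8e-05). Cell cycle genes had 35 of 49 higher, 38 adjusted over the list alone (median 0.39, adjusted p = 2e-06, adjusted p = 0.24 with an estimated correlation), such as the ribonucleotide reductase gene Rrm2 (147 to 272 CPM, 0.89 ± 0.08). Fibroblast identity was divided, 11 of 21 higher and 9 lower, also adjusted over the list alone (median 0.4, adjusted p = 0.026, adjusted p = 0.24 with an estimated correlation and 0.17 without LacZ neonatal replicate 2). NF-kB and complement lists were not called (adjusted p = 0.75 and 0.075).

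Aged and adult LacZ cells differed in interferon, complement and fibroblast genes. The test called 3231 genes, 1559 higher and 1672 lower in aged cells, 198 and 497 at least 2-fold. The count was 1892 without LacZ aged replicate 1. All 38 interferon response genes were lower, also adjusted over the list alone (median -3.43, adjusted p = 6.2e-187). Ifi44 (ENSMUSG00000028037, chromosome 3, 151730922 to 151749960) went from 159 ± 0.44 to 5.27 ± 1.7 CPM (-4.92 ± 0.17, adjusted p = 5.4e-13). Mx1 (-5.23 ± 0.4) and Rsad2 (-4.47 ± 0.2) fell with it, as did Ndufa4l2 (-5.17 ± 0.28), the acute phase gene Hp (184 ± 10 to 5.3 ± 1.4 CPM, -5.13 ± 0.17) and the inducible nitric oxide synthase gene Nos2 (-4.91 ± 0.47). The largest rise was in Cyp1a1 (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824), a P450 induced by the aryl hydrocarbon receptor, from 0.141 ± 0.2 to 9.08 ± 1.7 CPM (5.86 ± 0.45, adjusted p = 1.1e-08). The smooth muscle myosin gene Myh11 (3.2 ± 0.23), the homeobox gene Hoxc13 (2.45 ± 0.34), the actin nucleator Cobl (2.42 ± 0.19), Asb2 (2.32 ± 0.3) and Galnt18 (2.28 ± 0.14) also rose. NF-kB targets had 16 of 27 lower and 1 higher, 17 and 3 adjusted over the list alone (median -0.54, adjusted p = 6.1e-12), with the chemokine Ccl2 from 1360 to 561 CPM (-1.27 ± 0.08). Complement had 8 of 9 lower, 8 adjusted over the list alone (median -1.06, adjusted p = 1.7e-17). Fibroblast identity had 14 of 21 lower and 4 higher, also adjusted over the list alone (median -1.02, adjusted p = 1.1e-13), with decorin Dcn from 1850 to 598 CPM (-1.63 ± 0.1). Matrix had 17 of 24 lower and 2 higher, also adjusted over the list alone (median -0.57, adjusted p = 5.2e-11, adjusted p = 0.15 with an estimated correlation). Col3a1 (-1.71 ± 0.1), Col1a1 (-0.59 ± 0.1) and Postn (-0.82 ± 0.1) were among the genes that fell. Macrophage, endothelial, epicardial, sarcomere and imprinted lists were not called (adjusted p = 0.91, 0.29, 0.75, 0.3 and 0.29).

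Adult and neonatal MGT cells differed in 3567 genes (1672 higher, 1895 lower in adult), aged and neonatal in 4124 (1975 and 2149), and aged and adult in 2369 (1170 and 1199). Without MGT adult replicate 2 the first count was 2358. The third was 1436 without MGT adult replicate 1, 1080 without MGT adult replicate 2 and 1322 without MGT aged replicate 2. Of the genes higher in adult than in neonatal cells, 1146 were shared between vectors against 279.5 for independent lists, and of the lower ones 1376 against 362.7. Mmp3 again led in adult (930 ± 59 against 11.1 ± 1.8 CPM, 6.38 ± 0.14) and aged cells (697 ± 47 CPM, 5.97 ± 0.14), with Fgf10 (5.47 ± 0.2 and 5.48 ± 0.2). In adult cells Ly6k (5.88 ± 0.39) and Alpl (5.87 ± 0.25) rose too, and Ccl11 and the interleukin receptor gene Il1rl1 had ratios of 206 (36.5 to 8180) and 182 (32.3 to 7240). In aged cells Gsta3, of a family with shared sequence (5.78 ± 0.19), Cxcl14 (5.69 ± 0.28), Cyp1a1 (5.47 ± 0.38) and Akr1c18 (ratio 157, 43.0 to 1300) rose. Myh6 was at least 82.1-fold lower in adult MGT cells and lower by a ratio of 128 (35.1 to 1060) in aged ones. Gpm6a was lower by ratios of 292 (80.5 to 2420) and 304 (83.7 to 2510). Krt8 was lower by 176 (31.2 to 6990) in adult and at least 61.0-fold in aged cells. In adult cells Upk3b (-6.18 ± 0.17), Stk26 (-5.49 ± 0.34) and the anoctamin gene Ano5 also fell. In aged cells Gpc3 (-6.63 ± 0.29), Bnc1 (-6.42 ± 0.44) and Nrk (-6.29 ± 0.19) fell. Tnnt2 stayed lower in adult (-1.86 ± 0.14) and aged (-2.09 ± 0.14) than in neonatal MGT cells.

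Under MGT the endothelial, epicardial and imprinted lists were lower in adult (medians -2.82, -2.08 and -1.33) and aged (-3.36, -3.51 and -2.08) than in neonatal cells. Interferon response genes were lower in adult than in neonatal MGT cells, 25 of 38 with 1 higher, 27 and 1 adjusted over the list alone (median -0.54, adjusted p = 1.6e-05, adjusted p = 0.44 with an estimated correlation), and 15 lower without MGT neonatal replicate 1. They were lower still in aged cells, 37 of 38 against neonatal (median -2.75, adjusted p = 7.3e-80) and 35 of 38 against adult (median -2.13, adjusted p = 1.6e-132), 38 and 36 adjusted over the list alone. The regulator Irf7 fell by 3.57 ± 0.19 on the log2 scale from 131 ± 17 CPM in adult MGT cells, with Ifi44 (-4.33 ± 0.18), Rtp4 (-3.35 ± 0.19) and Oas2, which has close paralogs (-3.56 ± 0.28). The arginase gene Arg1 (-3.83 ± 0.41) and the growth factor gene Csf3 (-3.67 ± 0.38) fell there too. Cyp1a1 (3.65 ± 0.31), Myh11 (2.73 ± 0.21), Asb2 (2.38 ± 0.29), Hoxc13 (2.34 ± 0.31) and the skeletal actin gene Acta1 (2.07 ± 0.31) rose. Cdkn2a, an inhibitor that marks senescent cells, was higher in adult (0.53 ± 0.18, adjusted p = 0.034) and aged (0.85 ± 0.18, adjusted p = 0.00093) than in neonatal MGT cells. The adult call was lost without MGT neonatal replicate 2 (0.24) or MGT adult replicate 1 (0.62) or 2 (0.43).

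Whether the response to MGT itself depended on age was tested as the difference between log2 responses. Adult and neonatal responses differed in 536 genes (337 with the higher log2 change in adult cells, 199 in neonatal), aged and neonatal in 351 (277 and 74), and aged and adult in 284 (201 and 83). The 536 became 324 without LacZ neonatal replicate 1, 292 without replicate 2, 1408 without LacZ adult replicate 1, and 285 and 312 without MGT adult replicates 1 and 2. The 351 became 190 and 199 without the LacZ neonatal replicates, 220 and 232 without the LacZ aged ones and 183 without MGT aged replicate 2. The 284 became 704 (split evenly, 353 and 351) and 816 without the LacZ adult replicates, 112 without LacZ aged replicate 1, 115 and 173 without the MGT adult replicates and 129 without MGT aged replicate 2. Tnnt2 responded more in adult (4.75 ± 0.25, adjusted p = 9.6e-10) and aged (4.33 ± 0.25, adjusted p = 3e-09) than in neonatal cells, although its level under MGT was lower. Upk1b (ENSMUSG00000049436, chromosome 16, 38773184 to 38800328), a uroplakin of the mesothelium, rose from 0.845 to 33.7 ± 4 CPM in adult cells and went from 142 to 86.1 CPM in neonatal ones, a difference of 6.04 ± 0.22 (adjusted p = 3.4e-12), or 4.64 ± 0.2 for aged cells. Abi3bp (ENSMUSG00000035258, chromosome 16, 56477878 to 56690135), a matrix-binding gene linked to growth arrest, went the other way (-3.14 ± 0.39 and -3.86 ± 0.39), rising from 0.466 to 23.3 ± 2.7 CPM in neonatal and from 7.4 to 41.4 CPM in adult cells. The sarcomere list responded more in adult (7 of 27 called, 9 and 1 lower adjusted over the list alone, median 0.96, floored 0.75, adjusted p = 1.9e-11, 0.18 with an estimated correlation) and aged cells (5 called, 9 over the list alone, median 1.2, floored 0.78, adjusted p = 1.5e-09, 0.083 with an estimated correlation). Under MGT its mean stayed lower than in neonatal cells (3.45 to 3.62 against 4.73 and 5.02 log2 CPM). The epicardial list differed for adult (5 higher and 1 lower, 6 and 2 adjusted over the list alone, median 2.56, floored 0.92, adjusted p = 1.9e-11) and aged cells (4 higher, 4 and 1 over the list alone, median 1.44, floored 1.51, adjusted p = 3.1e-09).

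**Figure D3:**
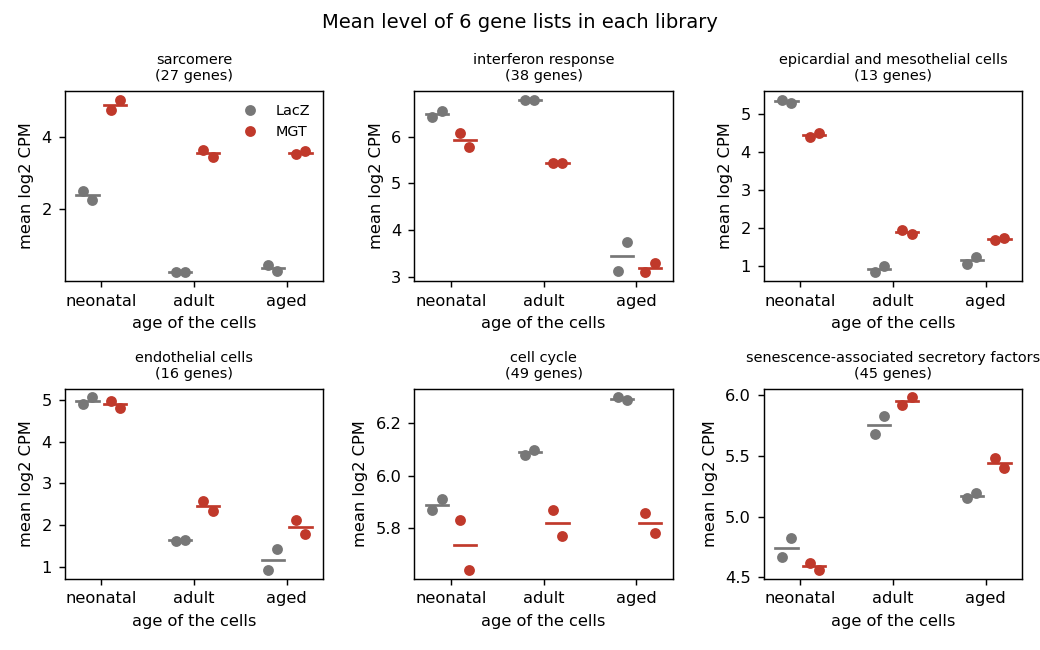
Mean log2 CPM of 6 gene lists in each library, by age (x axis) and vector (LacZ grey, MGT red). Points are libraries and bars are the means of 2 libraries, and the interferon response is lowest in aged cells under both vectors (median log2 change -3.43 against adult under LacZ).

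Interferon response genes fell more with MGT in adult than in neonatal cells, 18 of 38 called, 34 adjusted over the list alone (median -0.71, adjusted p = 2.1e-27, adjusted p = 0.2 with an estimated correlation), and DESeq2 called 9. The 18 became 8 without LacZ neonatal replicate 1 or MGT neonatal replicate 1, 10 without LacZ neonatal replicate 2 and 9 without either MGT adult replicate. Their log2 change lay higher in aged than in adult cells, 16 called, 34 adjusted over the list alone (median 0.88, adjusted p = 1e-44, adjusted p = 0.092 with an estimated correlation). That count ranged from 5 without MGT aged replicate 2 to 27 without LacZ aged replicate 2. It was 8 without LacZ aged replicate 1 and 10 without either MGT adult replicate or MGT aged replicate 1. Cell cycle genes fell more in aged than in neonatal cells (median -0.33, adjusted p = 3.5e-15, adjusted p = 0.083 with an estimated correlation). There 5 of 49 were called, 26 adjusted over the list alone, and none was called without LacZ neonatal replicate 1 or either LacZ aged replicate, 1 without MGT aged replicate 2, and 2 without LacZ neonatal replicate 2 or MGT neonatal replicate 1. The log2 change of matrix genes lay higher in aged than in adult cells, 7 of 24 called, 16 adjusted over the list alone (median 0.38, adjusted p = 1.3e-15, adjusted p = 0.11 with an estimated correlation). The 7 became 16 without LacZ adult replicate 2, 3 without LacZ aged replicate 1 or MGT adult replicate 1, and 4 without MGT adult replicate 2 or MGT aged replicate 2. Col1a1 responded more in aged than in neonatal cells (0.86 ± 0.14, adjusted p = 0.0013), and against adult cells the difference was not called (0.53, adjusted p = 0.055). Complement genes had a higher log2 change in aged than in neonatal (4 of 9, 8 adjusted over the list alone, median 0.65, adjusted p = 3.1e-09) and adult cells (6, 7 adjusted over the list alone, median 0.85, adjusted p = 3e-14), the 6 becoming 3 without LacZ aged replicate 1 or MGT adult replicate 1. The myofibroblast list responded more in aged than in neonatal cells (5 of 21, 8 and 1 lower adjusted over the list alone, median 0.35, adjusted p = 0.00017). That 5 was 3 without LacZ aged replicate 1 or MGT neonatal replicate 2, and 2 without LacZ aged replicate 2, either LacZ neonatal replicate or MGT aged replicate 2.

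Senescence, the arrest named in the study's title, was read from cell cycle inhibitors, p53 targets and the secreted factors of senescent cells. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), which encodes the inhibitor p21, was abundant in every group. MGT did not change it detectably in neonatal cells (684 ± 19 against 619 ± 4.6 CPM, 0.14 ± 0.07, adjusted p = 0.31). It rose slightly in adult (537 ± 12 against 453 ± 19 CPM, 0.25 ± 0.07, adjusted p = 0.021) and aged cells (681 ± 22 against 583 ± 7 CPM, 0.22 ± 0.07, adjusted p = 0.039), and the differences between ages were not called (adjusted p = 0.72, 0.78 and 0.96). The adult call was lost without MGT adult replicate 1 (0.22) or 2 (0.27), and the aged call without LacZ aged replicate 1 (0.24) or 2 (0.21) or MGT aged replicate 1 (0.23) or 2 (0.17). Under LacZ it was lower in adult than in neonatal cells (-0.45 ± 0.07, adjusted p = 7e-05) and higher in aged than in adult cells (0.36 ± 0.07, adjusted p = 0.00093), and aged did not differ detectably from neonatal (adjusted p = 0.37). Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653), which encodes p16 and p19, fell with MGT in neonatal cells (15.1 ± 0.55 to 8.54 ± 2.7 CPM, -0.82 ± 0.17, adjusted p = 0.0038), a call lost without MGT neonatal replicate 2 (-0.54). It fell in adult cells too (17.7 ± 0.59 to 12.4 ± 1.2 CPM, -0.52 ± 0.17, adjusted p = 0.037), lost without LacZ adult replicate 2 (-0.48) or MGT adult replicate 1 (-0.42) or 2 (-0.61), and in aged cells no change was detected (-0.18 ± 0.16, adjusted p = 0.5), while the differences between ages were not called (adjusted p = 0.63, 0.19 and 0.59). Its LacZ level did not differ detectably between ages (adjusted p = 0.3, 0.33 and 0.95). Inhibitors and markers as a list were called only for MGT in neonatal cells, where 2 of 11 fell, 2 also adjusted over the list alone. There the test pointed down (adjusted p = 0.033, adjusted p = 0.16 with an estimated correlation and 0.096 without MGT neonatal replicate 2) while the median was 0.03.

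Secreted factors tied to senescence differed between ages under LacZ, and less clearly with MGT. Under LacZ 26 of 45 were higher and 9 lower in adult than in neonatal cells, 27 and 10 adjusted over the list alone (median 0.93, adjusted p = 4.7e-10), such as the chemokine Cxcl5 (215 to 3200 CPM, 3.9 ± 0.15) and Il6 (119 to 709 CPM, 2.58 ± 0.13). Against adult cells, aged ones had 25 lower and 7 higher, 27 and 8 adjusted over the list alone (median -0.63, adjusted p = 5.5e-07, adjusted p = 0.08 with an estimated correlation), with Il6 at 208 CPM (-1.77 ± 0.13). With MGT in neonatal cells 13 fell and 5 rose, likewise adjusted over the list alone (median -0.09, adjusted p = 0.033, adjusted p = 0.39 with an estimated correlation). That list call was lost without LacZ neonatal replicate 2 (0.16, with 8 lower) or MGT neonatal replicate 2 (0.11). In adult cells the list was not called (15 higher, 13 lower, 16 and 15 adjusted over the list alone, adjusted p = 0.57), the 13 becoming 8 without MGT adult replicate 1. In aged cells 9 rose and 4 fell, 12 and 5 adjusted over the list alone (median 0.14, adjusted p = 0.044, adjusted p = 0.4 with an estimated correlation), lost without LacZ aged replicate 1 (0.077) or MGT aged replicate 1 (0.096), and the 4 became 2 without either of these or MGT aged replicate 2. Igfbp5, a growth factor binding protein, rose at every age (2.03 ± 0.18, 3.08 ± 0.18 and 2.93 ± 0.2), and Igfbp4 fell in neonatal cells (117 to 26.2 CPM, -2.15 ± 0.15). p53 targets were lower in adult than in neonatal LacZ cells, 19 of 26, 20 adjusted over the list alone (median -0.45, adjusted p = 2e-06), led by the apoptosis gene Pmaip1 (78.0 to 20.4 CPM, -1.94 ± 0.12), and were not called as a list for MGT (adjusted p = 0.93, 0.3 and 0.11). Across all 312 list tests 166 were called, and 61 of these held with an estimated correlation. Schwann cell, fatty acid oxidation and unfolded protein response lists were called in no comparison (smallest adjusted p = 0.51, 0.15 and 0.17). Too few members were measured to test histones (H1f3 and H1f4, the former lower in adult than in neonatal LacZ cells at -1.45), lymphocytes (Lck, under 1 CPM in every group) and sex-linked genes (Kdm5d), and no erythroid or mitochondrially encoded gene was tested.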

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

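The tests of interferon genes, of other lineages, of the delivered factors and of separate LacZ libraries below were chosen only after the results were seen. The response to MGT differed between ages, by an edgeR test of the difference itself, in 536 genes for adult minus neonatal cells, 351 for aged minus neonatal and 284 for aged minus adult. These counts ran from 285 to 1408, 183 to 298 and 112 to 816 when 1 library was left out.

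By that test Tnnt2 (4.75), Lrrc2 (6.71), Nppa (3.02) and Myl7 (at least 4.88) had a higher log2 change with MGT in adult than in neonatal cells. So did the delivered Mef2c (0.94) and Tbx5 (1.37), vector transcripts included, and Upk1b (6.04), Krt18 (5.26) and Plet1 (5.05), while Abi3bp (-3.14), Mx1 (-2.99), Rrad (-2.12), Cyp7b1 (-1.9), Cxcl10 (-1.8) and Postn (-0.6) had a lower one. Against 1 to 3 counts the fold of folds had counting intervals of 18.8 to 4130 for Lrrc2, 13.1 to 186 for Krt18 and 11.4 to 161 for Plet1. Calls were lost without LacZ neonatal replicate 1 (Tbx5 1.21, Postn -0.6), LacZ neonatal replicate 2 (Cyp7b1 -1.66, Nppa 2.78, Postn -0.61), MGT neonatal replicate 2 (Cyp7b1 -1.68), LacZ adult replicate 2 (Tbx5 1.08, Nppa 1.98), MGT adult replicate 1 (Tbx5 1.35, Nppa 3.08) or MGT adult replicate 2 (Cyp7b1 -1.8, Nppa 2.97, Postn -0.49). In aged minus neonatal cells Tnnt2 (4.33), Myl7 (6.05, 11.9 to 2620), Lrrc2 (5.13, 9.68 to 289), Kank4 (4.9, 10.2 to 145), Upk1b (4.64), Tbx5 (2.02), Col1a1 (0.86) and Mybpc3 (at least 2.24) had the higher change, and Abi3bp (-3.86), Fras1 (-3.04), Rrad (-2.16), Dkk2 (-1.84) and Dlk2 (-1.78) the lower. The Mybpc3 call was lost without any 1 of 7 libraries, and calls of Fras1 (-2.42) and Tbx5 (1.72) without LacZ aged replicate 1. Without LacZ aged replicate 2 Rrad (-1.79) and Dlk2 (-1.5) were lost, Dlk2 also without LacZ neonatal replicate 1 (-1.48), either MGT neonatal replicate (-1.76 and -1.81) or MGT aged replicate 1 (-1.55).

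Between aged and adult cells the changes of Mx1 (4.27), Rsad2 (2.64), Cxcl10 (2.61), Pdlim3 (3.49), Ndufa4l2 (2.85) and Postn (0.8) lay higher in aged cells, whereas those of Dkk2 (-2.24), Chrna7 (-2.11), Dlk2 (-1.83), Flt1 (-1.82) and Sprr2h (-1.49) lay lower. Calls were lost without MGT aged replicate 1 (Mx1 3.98, Ndufa4l2 2.75, Chrna7 -2.16, Dlk2 -1.59, Sprr2h -1.34), MGT aged replicate 2 (Mx1 4.5, Ndufa4l2 2.93, Cxcl10 2.3, Chrna7 -2.08), LacZ aged replicate 1 (Flt1 -1.58, Sprr2h -1.16), LacZ aged replicate 2 (Chrna7 -1.6, Dlk2 -1.56), LacZ adult replicate 2 (Chrna7 -1.73), or MGT adult replicates 1 (Chrna7 -2.15, Dlk2 -1.81, Sprr2h -1.46) and 2 (Chrna7 -2.08). Lists called with either correlation differed in the epicardial genes (median 2.56 for adult and 1.44 for aged against neonatal), complement (0.65 for aged minus neonatal, 0.85 for aged minus adult) and myofibroblast genes (0.35 for aged minus neonatal).

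A lower starting level is open as a cause of the larger adult response. Of the 286 genes that rose with MGT in adult cells with a larger response there, 75.5% were lower in adult than in neonatal LacZ cells and 33.2% higher in adult than in neonatal MGT cells. The first share cannot decide, as that LacZ difference helped choose the genes. Chosen on LacZ replicate 1 or 2 and tested on the other, it was 67.9% or 45.3%. All tested genes had 18.4% or 11.9%, and this tie remained. More of the delivered factors in adult cells is open too: their median was 0.07 in adult against neonatal MGT cells, but they went both ways (Tbx5 0.23, Gata4 -0.27). Age itself, apart from preparation, and mesothelial cell loss with MGT stay open and untested.

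Lower interferon genes in aged than in adult cells could come from immune cells in the adult preparations, but macrophage markers differed by a median of only 0.03. Less virus in the aged cultures stays open: in MGT cells the delivered factors had a median of -0.07 but Mef2c was lower (-0.32). LacZ vector was not measured in LacZ cells (interferon median -3.43). The interferon median was -2.13 under MGT as well, so age and another difference between preparations, such as an infection or culture conditions, cannot be told apart.

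Other lineages were higher in neonatal LacZ cells. A lower share of fibroblasts alone would raise every other cell type alike, but endothelial markers had a median of -3.84 in adult against neonatal cells and macrophage markers 0.36. The macrophage call was lost with an estimated correlation (adjusted p = 0.54) or without LacZ neonatal replicate 1 (0.13), but the gap between the lists far exceeds the -0.32 between LacZ neonatal replicates. Carried-over cardiomyocytes as the source of neonatal Tnnt2 (285 CPM) are argued against by 0 of 5 other abundant cardiomyocyte transcripts lying within 10-fold of it, the highest being Myl7 at 8.74 CPM. A change in the lineages themselves with age, or in how the preparations were made, may remain and was not tested.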

How the results depend on the processing

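Column sums as library totals, and voom with quality weights per group, were chosen after seeing the data, the latter because the LacZ adult libraries differed most. RLE size factors, DESeq2, a mean of at least 5 CPM and column sums kept each count of called genes within 1.5 times of its value. RLE and column sums changed no list call, and neither moved the median of all genes by more than 0.011. The 532 named gene calls were mostly picked for large changes or low p. In all alternatives run on them 477 held, 55 were lost in at least 1 and none reversed. Of 166 called list tests 61 kept the call in all, and 105 lost it with an estimated correlation.

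Without a filter on low counts the differences between ages called 810 (adult minus neonatal), 635 (aged minus neonatal) and 539 (aged minus adult) genes, since more genes were tested. With only the compared groups in the fit, which leaves fewer samples for the spread, MGT called 1688 genes in neonatal and 1550 in adult cells, aged against adult LacZ 1897, and aged minus neonatal 669. Voom with weights called 1817 for MGT in neonatal cells and 647 for aged minus neonatal, and the cause was not tested. The share of those with the higher change in aged cells was then 68.6%, and 68.3% with the compared groups only, against 78.9%. Over genes with a mean of at least 5 CPM, fewer noisy genes enter, and responses correlated at 0.744 (adult and neonatal), 0.712 (aged and neonatal) and 0.845 (aged and adult).

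Leaving out each library in turn, with the lone library assumed to vary like the other groups, gave ranges whose cause was not tested beyond the smaller sample. MGT called 628 to 912 genes in neonatal, 1475 to 3571 in adult and 1196 to 1951 in aged cells. Aged against adult LacZ cells gave 1892 to 3846. Under MGT, adult against neonatal gave 2358 to 2756 and aged against adult 1080 to 1915. The differences gave 285 to 1408 (adult minus neonatal), 183 to 298 (aged minus neonatal) and 112 to 816 (aged minus adult). The correlations ran from 0.502 to 0.551 (adult and neonatal), 0.485 to 0.53 (aged and neonatal) and 0.64 to 0.695 (aged and adult). List tests reversed 3 times: oxidative phosphorylation for aged minus adult without LacZ adult replicate 1 (0.92, range to 1.6e-10) and for adult minus neonatal without LacZ adult replicate 2 (0.69, range to 1.6e-07), and interferon response for aged minus neonatal without LacZ aged replicate 1 (0.27, range 1e-11 to 0.35).

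The replicate numbers did not pair the libraries: same-numbered ones deviated together at r = 0.016 (neonatal), 0.048 (adult) and 0.007 (aged). With the replicate block MGT called 1172, 2583 and 2397 genes in neonatal, adult and aged cells, and the differences 622, 435 and 375. Under the block the calls of Cdkn1a in aged cells (0.22) and of the calcium list in adult against neonatal LacZ cells (0.051) were not made, and calls were added for Mef2c (0.67) and Nppa (5.61) in aged minus neonatal, Col1a1 (0.52) and myofibroblast genes (0.048) in aged minus adult. It changed no other call among those named.

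Depth limits genes under 0.16 to 0.2078 CPM in a library, and fold changes against 0 counts are lower bounds.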

Other observations

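The tests of X-linked genes and of aryl hydrocarbon receptor targets below were written before their results were seen, on patterns noticed in these data. Kdm5d, Cyp1a1 and Ahrr differed between some of the ages. Kdm5d, a Y-linked demethylase gene, lay at 14.4 CPM in neonatal, 33.2 in adult and 32.2 in aged LacZ cells (adult against neonatal 1.2 ± 0.13, adjusted p = 5.4e-07). Genes on the X chromosome that escape inactivation were mostly lower in adult than in neonatal LacZ cells (Kdm6a -0.51, Kdm5c -0.68 and Eif2s3x -0.48 called, Ddx3x -0.16 and Pbdc1 0.06 not). Their median of -0.48 is consistent with neonatal cultures pooled from both sexes and adult ones mostly male, a hypothesis that the labels do not address. In aged against neonatal cells only Kdm6a and Kdm5c (-0.57 each) were called.

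Ahrr, the repressor induced by the aryl hydrocarbon receptor, rose with Cyp1a1 in aged against adult LacZ cells (2.48 to 11.3 CPM, 2.19 ± 0.2, adjusted p = 1.1e-07). Of 6 other tested target genes 3 were higher (Cyp1b1 0.39, Tiparp 0.63 and Nqo1 1.99) and Aldh3a1 was lower (-1.86), so activity of the receptor may contribute in aged cells. In adult against neonatal LacZ cells 5 of 6 were higher but Cyp1a1 fell (-3.08, to 5 counts), so targets parted from it. Under MGT it rose (1.82). Cyp1a1 and Ahrr were seen first.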
